A study of Zea mays subsp. mays with 5 samples.

How the data were processed

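Parallel analysis of RNA ends (PARE, also called degradome sequencing) reads a short tag from the 5′ end of polyadenylated RNA fragments that carry a 5′ monophosphate. Such fragments arise when a small RNA directs slicing of its target and also during general decay. Slicing falls opposite nucleotides 10 and 11 of the small RNA, so the tag of a sliced target begins with the reverse complement of nucleotides 1 to 10. The series holds 5 maize libraries. According to the labels 1 came from pollen of the inbred B73, 1 from pollen of the mop1 mutant, and 3 from the inbred W23: anthers of 1.0 and 1.5 mm pooled, anthers of 2.0 to 3.0 mm pooled, and anthers of 4.0 mm pooled with pollen. Groups were taken from the sample titles. Another label field gives anther as the source of every library, pollen included. The genetic background of the mop1 plants is not given in the sources used here, and the growth protocol describes W23 plants and other mutants but neither B73 nor mop1.

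The deposited files hold counts: each lists every distinct tag of 18 to 20 nucleotides with the whole number of times it was read, with no header and no gene names. Bowtie and TopHat are named in the submitters' processing notes with no version or role. How adapters were removed and which genome build was used are not given in the sources used here. The deposited counts were not normalized. For comparison they were scaled to TPM, the tags a library would hold if its total were 1000000. The totals ranged from 38138281 to 88342367 tags per library.

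Each group had 1 library, so no difference between groups could be set against a replicate spread, no test across conditions was run and no p-value is given. Counts carry exact Poisson 95% intervals, ratios of scaled counts carry exact conditional binomial 95% intervals, and shares carry Wilson 95% intervals. PCR copies cannot be told from separate molecules in these files, so intervals and floors cover counting error only. A count of 0 was taken to allow up to 3 tags, which is 0.0340 TPM in the deepest library and 0.0787 in the shallowest.

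No genome or transcript sequence was used here. Tags are therefore reported by sequence, and no tag was given a gene name, a chromosome or a position. The planned comparisons of genes between anther stages and between mop1 and B73, the level of the mop1 gene itself, the fixed gene lists, the codon periodicity, the search of transcripts for target sites and the search of the genome for phasiRNA loci all need such sequence and were not run. The rule for named items fixed before the data were examined provides for this case the 10 most abundant tags of each library. For each miRNA family it names the target with the highest tag count at the cut position, which needs transcript sequence. Naming the tag with the highest count at the cut position in its place was chosen after the data were seen.

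The cleavage signature was counted as planned for 32 small RNAs of 28 families, whose mature sequences were written down from general knowledge before the data were examined. The tags that start with the reverse complement of nucleotides 1 to 10, called the word of that small RNA below, were counted in each library. The background was the mean count of the same word 1 to 8 nucleotides further into the tag. To describe how unusual a ratio to background is, every other word of 10 nucleotides with the same first base and a similar background in the same library served as a reference, and a small RNA was called above background when at most 0.1% of reference words had as high a ratio. At that limit 0.032 of the 32 words per library are expected above background by chance. This comparison with reference words was added after the data were seen. Other versions fixed before the data were examined used a word of 9 nucleotides, 1 mismatch allowed, distinct tag sequences in place of counts, and a background from 100 shuffled words. Ratios of distinct sequences between libraries were scaled by total tags, although distinct sequences need not grow in proportion to them.

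Because 10 nucleotides leave many chance matches, longer sites were rebuilt from the tags themselves, a step added after the data were seen. For tags with at least 5 reads in a library, the bases upstream of the cut were read from overlapping tags of all 5 libraries, with an overlap of at least 14 nucleotides. A base was followed where at least 50% of the overlapping tag counts gave it. The whole site was then scored against the small RNA with the planned rule: 1 for a mismatch, 0.5 for a G:U pair, doubled at nucleotides 2 to 13, nucleotides 10 and 11 paired, and a total of at most 4. The settings for overlap and base share were picked from 8 combinations after their yields on the real small RNAs and on 3 shuffled sets had been seen. The yields with all 8 are in the closing section. As a control, 10 other sets of shuffled small RNAs that kept each dinucleotide count were searched in the same way. Where several loci share the first bases downstream of the cut, their upstream bases cannot be separated, so a rebuilt site is a consensus and may stand for more than 1 locus.

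Tags were also compared between pairs of libraries. For this, tags with a run of at least 14 A were left out, 1 TPM was added to each value, and tags with at least 10 TPM in either library were counted when they differed at least 4-fold. Tags that overlap within 6 nucleotides were joined into groups, because neighbouring tags of 1 transcript are not independent. Tags named from these comparisons, or as specific to a W23 library, were chosen after their values were seen. This comparison replaced the planned comparison of genes and was set up after the data were seen.

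The scripts ran under Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. The searches were tested on simulated transcripts with planted cuts. There the site search recovered 75 of 96 planted sites and reported 0 others. The word comparison called 32 of 32 small RNAs with planted cuts and 0.05% of random words. These rates describe the simulation only and need not carry over to the maize libraries. In those libraries the sets of shuffled small RNAs gave a mean of 3.6 sites (1 to 7).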

Results

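The series profiled the 5′ ends of cleaved and decaying polyadenylated RNA in maize male reproductive tissue by PARE, to find where small RNAs cut their targets while phased small interfering RNAs (phasiRNAs) are made. PhasiRNAs are produced from long precursor transcripts after a first cut by a trigger miRNA: miR2118 for the 21-nucleotide class and miR2275 for the 24-nucleotide class. The 5 libraries held 63454337 tags from B73 pollen, 88342367 from mop1 pollen, 50968596 from W23 anthers of 1.0 and 1.5 mm, 38853899 from W23 anthers of 2.0 to 3.0 mm and 38138281 from W23 anthers of 4.0 mm with pollen. With 1 library per group there is no replicate check on any difference below, and each compares libraries, not conditions.

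The libraries differed in makeup before any comparison of cleavage. Distinct tag sequences numbered 4856811 in B73 pollen and 10637242 in mop1 pollen. They numbered 12402402 in the 1.0 and 1.5 mm library, 10432849 in the 2.0 to 3.0 mm library and 8485160 in the 4.0 mm and pollen library. At the common depth of 38138281 tags the expected number was still lower in the pollen pair, at 3618210 for B73 and 5979660 for mop1, than in the W23 libraries, where the lowest was 8485160. Tags with a run of at least 14 A made up 15.2% of B73 pollen (15.1 to 15.2) and 14.1% of mop1 pollen (14.1 to 14.1), against 0.0984%, 0.164% and 0.0954% of the W23 libraries in order of anther length. The most abundant tag of both pollen libraries was AAAAAAAAAAAAAAAAAAGT, with 4205487 and 4246323 reads. Among the 10 most abundant tags of each pollen library only 1 lacked such a run, TACCTGGTTGATCCTGCCAG, which was also among the 10 most abundant of every W23 library with 24988, 28011 and 13815 reads.

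Some of the most abundant tags of the W23 libraries differed between stages and others were shared. In the 1.0 and 1.5 mm library the top tag, GAACACTTGCCTCGGATTGA, was read 109457 times, against 9738 and 6303 times in the later libraries and 0 times in either pollen library. In the 2.0 to 3.0 mm library GTGAACCAAATGAGCTTATG was read 53380 times and GCAAACTGAAATGATAAAGA 42654 times. The same tags had 48 and 99 reads in the 1.0 and 1.5 mm library and 26 and 24 in the 4.0 mm and pollen library. The first 10 bases of GTGAACCAAATGAGCTTATG lie 2 mismatches from the nearest miR2275 word and those of GCAAACTGAAATGATAAAGA 1 mismatch. The third most abundant tag of that library, TCGTTAATTATGTAAGCATT, was read 34836 times and has 9 mismatches to the nearest miR2275 word and 5 to the nearest miR2118 word. In the 4.0 mm and pollen library the top tag was TATCGAGTAGACCCTGTCGT with 46760 reads, and it was also the third most abundant at 1.0 and 1.5 mm with 24431 reads, against 4240 at 2.0 to 3.0 mm. CGACACGACTCTCGGCAACG was among the 10 most abundant of all 3 W23 libraries with 21904, 24282 and 27218 reads, and ATCATGCATTGGATGGATGC had 13728, 16073 and 8221.

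The cleavage signature asks in which libraries tags begin where a miRNA would cut. The phasiRNA triggers stood out in the anthers of 2.0 to 3.0 mm. There, 6500 tags (167 TPM, interval 163 to 171) began with a miR2275 word, against a background of 230, and 4669 (120 TPM, 117 to 124) with a miR2118 word, against 147. Of the 6500 tags 6397 began with the miR2275a word and 103 with the miR2275b word, which was not above background and had 1.85 times its shuffled mean. miR160, which targets auxin response factors, was the other family above background in that library, with 145 tags against 9.25. In the 1.0 and 1.5 mm library miR2118 alone passed, with 430 tags against 196, and 185 of them were the single tag GCATTAGGAAGCTGTAGGCC. In the 4.0 mm and pollen library miR156, which targets SBP-box transcription factors, had 378 tags against 77.4 and miR160 had 65 against 8.5. In B73 and mop1 pollen 0 of the 28 families stood above background by the comparison with reference words. Set against shuffled words instead, miR396, miR444, miR2118 and tasiR-ARF reached at least 3 times the shuffled mean in both pollen libraries. For miR2118 this held for the miR2118b word alone, at 7.35 and 4.12 times, and not for miR2118a (0.241 and 0.251) or miR2118c (0.479 and 0.487). A single tag gave 58 of the 81 miR2118b tags in B73 pollen, and another gave 59 of the 95 in mop1 pollen. The miR444 words, the most abundant there with 2354 and 3053 tags, rested on 1 tag: AACAACTGCATGGCTCTTGC had 2260 reads in B73 pollen, 2808 in mop1 pollen and 1492 in the 4.0 mm and pollen library. With 1 mismatch allowed only miR2118 and miR2275 in the 2.0 to 3.0 mm library were above background, and with distinct sequences miR2118 in the 1.0 and 1.5 mm library stayed above it as well. With a word of 9 nucleotides miR528 was above background in every W23 library, miR169 in all but the 2.0 to 3.0 mm library, and miR2118 and miR2275 in the 2.0 to 3.0 mm library, while miR156 and miR160 were not above it in any.

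**Figure D1:**
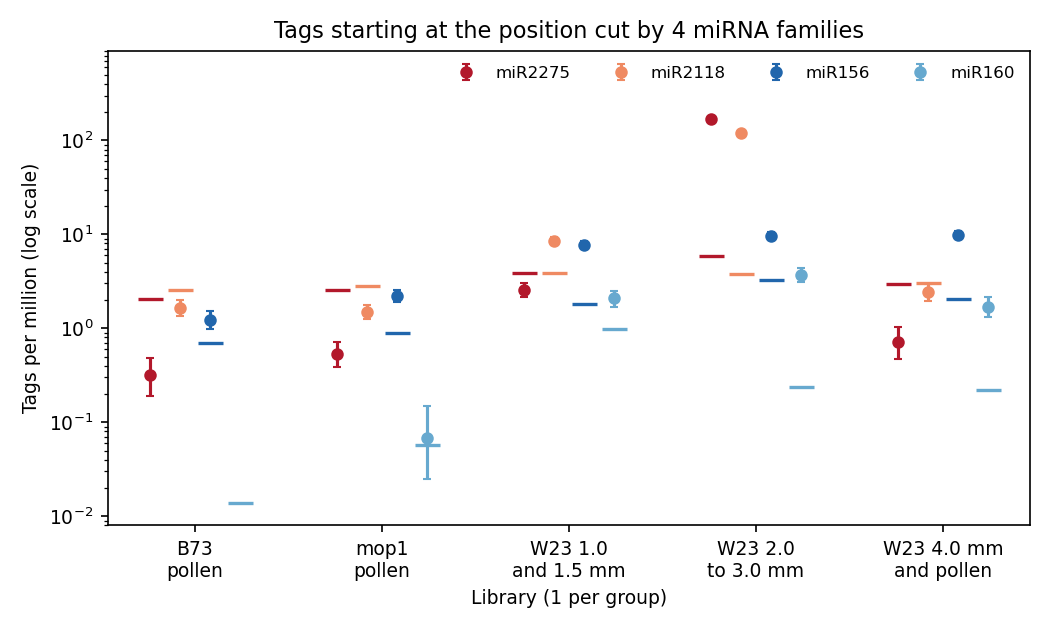
TPM (vertical axis, log scale) that begin with the word of miR2275, miR2118, miR156 or miR160 in each library (horizontal axis, 1 library per group). Points are values with exact Poisson 95% intervals for counting error, and short bars are the background of the same word 1 to 8 nucleotides further into the tag. miR2275 and miR2118 reach 167 and 120 TPM in the W23 2.0 to 3.0 mm library, and miR160 had 0 tags in B73 pollen, so no point is drawn there.

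The comparison of stages asks when tags that begin with each word are frequent. The miR2275 words were 65.1 times as frequent at 2.0 to 3.0 mm as at 1.0 and 1.5 mm (54.7 to 78.0) and 236 times as frequent as at 4.0 mm with pollen (162 to 359). For miR2118 the ratios were 14.2 (12.9 to 15.8) and 49.3 (40.1 to 61.2). Both families kept a ratio above 1 without their 10 most abundant tags, but at lower sizes: 4.22 and 9.33 for miR2275, and 8.52 and 18.7 for miR2118. Counted as distinct sequences, the miR2275 ratios were 3.48 and 6.99 and the miR2118 ratios 2.75 and 4.83. Of the 20 families with at least 20 tags in each of the first 2 stages, 7 had an interval above 1 (miR156, miR160, miR164, miR171, miR390, miR2118 and miR2275) and 2 below it (miR408 and miR444), and the median ratio was 1.19. Of these 7, miR160, miR2118 and miR2275 were above background at 2.0 to 3.0 mm by the reference words. The others were not, and miR390 had 100 tags against a background of 160. At rebuilt sites miR390 had 53 and 34 tags and miR164 had 4 and 0. Among families with fewer tags miR167 went from 16 to 93 tags, a ratio of 7.62 (4.46 to 13.9), but 78 of the 93 were the single tag GGCAGCTTCATATGTGAGTA. It was not above background by the reference words, and at 2.0 to 3.0 mm it had 3.76 times the mean of shuffled words. Between 4.0 mm with pollen and 2.0 to 3.0 mm, 19 families were compared, with a median ratio of 0.631. An interval below 1 was found for 9 and above it for 2 (miR444 and tasiR-ARF), so words of some families other than the triggers also fell. Among the 9 only miR160, miR2118 and miR2275 were above background at 2.0 to 3.0 mm by the reference words. At rebuilt sites of families other than the triggers the ratio was 1.38 (1.28 to 1.50), from 1112 tags at 2.0 to 3.0 mm and 1509 at 4.0 mm with pollen. At 1 miR169 site alone the tags went from 14 to 447, so this ratio rests largely on that site.

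Rebuilding longer sites from overlapping tags gave 53 distinct sites of 17 families with a penalty of at most 4, against a mean of 3.6 for the 10 shuffled sets (1 to 7). When the cut was assumed at other positions of the miRNA the same search gave between 4 and 13 sites. In 46 of the 53 the cut position held the most tags among the tag starts that could be read within 10 nucleotides of it. At some sites, among them the leading miR169 and miR2275 sites, only the cut and starts upstream of it could be read. Of these sites, 37 belonged to families other than the phasiRNA triggers and 16 to miR2275, and 0 sites of miR2118 were rebuilt, against 2 at a penalty up to 5. The number of miR2275 sites fell to 1 when a base needed 80% of the overlapping counts, and tags 1 mismatch apart counted once left 11. Many of the 16 share the same upstream bases, and some of their tags differ at 1 base or end in an A run. They therefore need not be 16 separate sites.

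**Figure D2:**
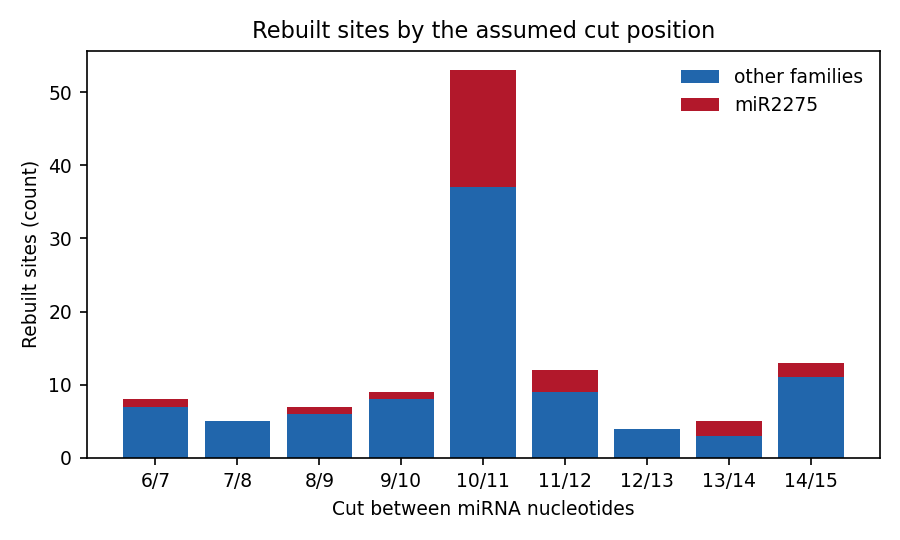
Number of rebuilt sites (vertical axis) when the cut is assumed between each pair of miRNA nucleotides (horizontal axis), with families other than miR2275 in blue and miR2275 in red stacked above them. The bar at nucleotides 10 and 11 reaches 53 sites, and the other bars lie between 4 and 13.

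The sites of conserved miRNAs as a set had tags in all 3 W23 libraries. For 6 of the 16 families (miR164, miR319, miR396, miR444, miR528 and miR529) at least 1 of the 10 shuffled sets gave as many sites, so these families are not beyond chance by their number of sites. In all, 7 sites of miR169, miR319, miR390, miR396, miR528 and miR529 lay at the penalty limit of 4. miR169, whose targets encode NF-YA subunits, had 6 rebuilt sites with 798, 506 and 991 tags in order of anther length. The 4.0 mm and pollen library had 2.00 times the frequency of the 2.0 to 3.0 mm library at these sites (1.79 to 2.23). Without the site with the most tags the ratio was 1.13 (0.995 to 1.28), from 492 and 544 tags, and 3 of the remaining 5 sites were less frequent in the 4.0 mm and pollen library. The miR169 site with the most tags, GTGGCAACTCA followed after the cut by TCCTTGGCTCTTGGAACTTT, had 131, 14 and 447 tags. In the last library 98.9% of the tags read there began at the cut, but no starts downstream of the cut could be read. miR156 had 8 sites with 315, 294 and 271 tags, led by GTGCTCTCTC followed by TCTTCTGTCATGCAGGACGC with 122, 204 and 75 tags. miR172, which targets AP2 transcription factors, had 3 sites with 84, 53 and 66 tags, led by TGCAGCATCA followed by TCAGGATTCTCTACCGCCGC. The 3 miR160 sites had 36, 65 and 37 tags, and the leading one was AGGCATACAGG followed by GAGCCAGGCATGCTCAATTT. For miR394, whose target is an F-box protein, GGAGGTGGAC followed by AGAATGCCAAATCTCTGGTG pairs with a penalty of 0 and had 34, 17 and 11 tags. Sites of miR390, which cuts TAS3 precursors, had 53 and 34 tags in the first 2 stages and 2 in the 4.0 mm and pollen library, where their frequency was 0.0599 of that at 2.0 to 3.0 mm (0.00698 to 0.234). Both miR390 sites lay at the penalty limit, and at the one with 5, 0 and 0 tags only 9.26% of the tags read around it began at the cut. The site of miR393, which targets auxin receptors, went the same way with 27, 22 and 3 tags, while sites of miR164, which targets NAC transcription factors, had 4, 0 and 26, with 12.7% of the tags around the weaker of its sites at the cut.

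miR159 had TGGAGCTCCCT followed by TCACTCCAAGATACTGAATC with 23, 15 and 13 tags, and a miR319 site 1 nucleotide away had 5, 4 and 4. miR166 had TTGGGATGAAG followed by CCTGGTCCGGATTCAGTTGG with 29, 14 and 9 tags, and miR528 had CTGTTTTGCAT followed by GCTCCTTCCACAACTTGTAG with 29, 20 and 22. The miR171 site GATATTGGCGC followed by GGCTCAATCACCAGCTTCCC and the miR444 site AAGCTTGAGAC followed by AACAACTGCACAACTTGCAA both pair with a penalty of 0. They had 12, 6 and 3 tags and 19, 4 and 1 tags. miR529 had 17, 34 and 18 tags at 1 site and miR396 had 11, 4 and 1.

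The 16 rebuilt miR2275 sites held 82, 14424 and 11 tags in the W23 libraries, or 371 TPM at 2.0 to 3.0 mm (365 to 377). That is 231 times the frequency at 1.0 and 1.5 mm (186 to 290) and 1287 times that at 4.0 mm with pollen (719 to 2579). All 16 had at least 5 tags at 2.0 to 3.0 mm, 7 had as many at 1.0 and 1.5 mm and 0 at 4.0 mm with pollen. A site was kept only if its tag had at least 5 reads in some library. Each of the 16 was most abundant at 2.0 to 3.0 mm, so these counts and ratios follow in part from how the sites were picked. The leading site was TGGATTATTAGA followed by GGGAACTGAAACCAGATCCA, with 6, 5426 and 4 tags. TGAGATATTAGA followed by GGAAACTGATAGTAGCTGAT pairs with miR2275b at a penalty of 1 and had 6, 2633 and 2 tags. TGAACTATTGGA followed by GGAAACCAAAACACCTGTCA pairs with miR2275a at a penalty of 2 and had 6, 2497 and 4. Over the same libraries the 37 sites of the other families had 30.0, 28.6 and 39.6 TPM, and their ratio between the first 2 stages was 0.955 (0.883 to 1.03).

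**Figure D3:**
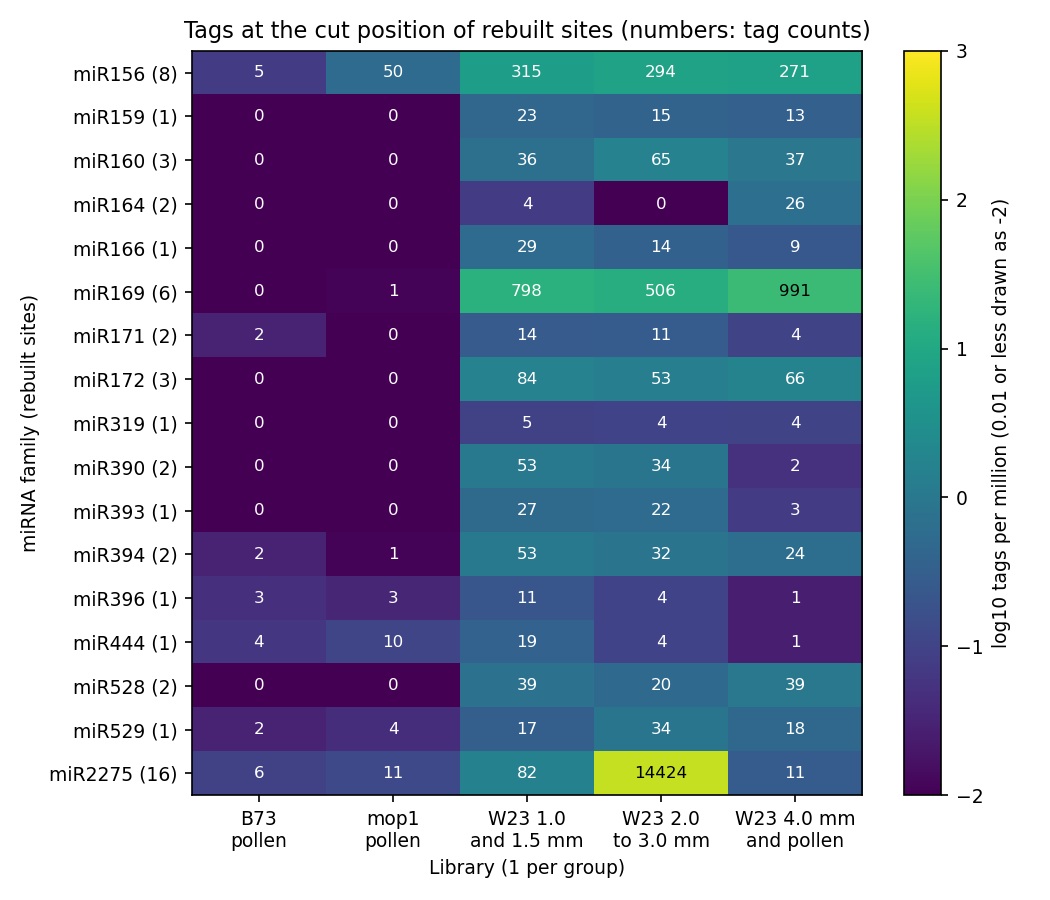
Tags at the cut position of rebuilt sites by miRNA family (rows, with the number of sites) and library (columns, 1 per group). Colour gives log10 TPM and the printed numbers are tag counts. miR2275 has 14424 tags in the W23 2.0 to 3.0 mm library and 82 or fewer elsewhere, and the B73 and mop1 pollen columns hold 50 or fewer tags in every row.

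The comparison of mop1 with B73 pollen concerns the loss of an RNA-dependent RNA polymerase of the heterochromatic siRNA pathway, which MOP1 encodes. Tags at the conserved sites were rare in both libraries although these were the deepest. At the 37 sites B73 pollen had 18 tags (0.284 TPM, 0.168 to 0.448) and mop1 pollen 69 (0.781, 0.608 to 0.988), against at least 28.6 TPM in the W23 libraries. None of these sites had 5 tags in B73 pollen and 2 had as many in mop1 pollen. Sites were kept only if their tag had at least 5 reads in some library, and nearly all of the 37 passed through W23 libraries. The low pollen counts therefore follow in part from how the sites were picked. One miR156 site, GTGCTCTCTC followed by TCTTCTGTCAACTCAGCCAT, gave 49 of the 69 mop1 tags and had 1 tag in B73 pollen. Plant line and any difference in library preparation coincide here, and the 1 W23 library with pollen also holds anthers. The gap between the pollen pair and the W23 libraries therefore cannot be assigned to line, tissue or preparation. Among the words, 12 families had at least 20 tags in both pollen libraries, and the mop1 to B73 ratio lay between 0.636 for miR529 and 1.80 for miR156 (1.37 to 2.37). The miR156 ratio turned to 0.857 with 1 mismatch allowed and to 0.869 for distinct sequences, and 110 of the 195 mop1 tags for miR156 were the single tag TCTTCTGTCAACTAAAAACG. The value for distinct sequences depends on scaling by total tags, of which mop1 pollen had more. No word of either pollen library was above background by the reference words, while 4 families had a word at least 3 times the mean of its shuffled words in each, miR2118 by the miR2118b word alone.

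Tags compared by sequence differed strongly between the W23 libraries. Of 5169 tags with at least 10 TPM at 2.0 to 3.0 mm or at 1.0 and 1.5 mm, 835 (in 468 groups of overlapping tags) were at least 4-fold higher and 2380 (in 253 groups) at least 4-fold lower at 2.0 to 3.0 mm. The balance depends on the unit: more were lower by tag, and more were higher by group. Among tags with at least 50 TPM the largest rise was that of GTGAACCAAATGAGCTTATG, at 1374 against 0.942 TPM, or 9.47 on the log2 scale with 1 TPM added. Between 4.0 mm with pollen and 2.0 to 3.0 mm, 7834 of 10626 tags (781 groups) were higher and 2187 (751 groups) lower at 4.0 mm with pollen. There the largest fall was again that of GTGAACCAAATGAGCTTATG, to 0.682 TPM, and the largest rise was that of AGGCATGCTGGCAGTTACTA, from 0.206 to 237 TPM.

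Of the tags at least 4-fold higher at 2.0 to 3.0 mm than in both other W23 libraries, 826 in all, 15 began within 1 mismatch of a miR2275 word and 10 within 1 mismatch of a miR2118 word. At offsets 1 to 8 of the same tags the mean was 0 for both. The 15 and 10 tags held 8.11% and 0.683% of the summed frequency of the 826. In the other W23 libraries 0 and 2 specific tags began within 1 mismatch of a miR2275 word, out of 2198 and 7303. Of the 7303 tags specific to 4.0 mm with pollen, 57.0% reached 10 TPM in B73 pollen and 57.0% in mop1 pollen. For the tags specific to the other stages these shares were at most 0.363%.

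Between mop1 and B73 pollen 14270 tags were compared, and 1758 (532 groups) were at least 4-fold higher and 1386 (227 groups) at least 4-fold lower in mop1. Among tags with at least 50 TPM the one with the largest rise, AACACTTAATTGTATTGCAT, was at 290.0 against 2.52 TPM, and the one with the largest fall, TTTCTGTAATCCTGCCTGAT, at 0.509 against 241. Tags with a sequence close to the latter went both ways: GTTTCTGTAATCCTGCCTGA had 54 reads in mop1 and 12647 in B73 pollen, and GTGTCTGTAATCCTGCCTGA, 1 mismatch from it, had 12663 and 78. Of the tags with at least 10 TPM in either library, 51.5% reached that level in both. For B73 pollen against W23 4.0 mm with pollen this share was 28.1%, and against the 2 earlier W23 stages 0.287% and 0.413%.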

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

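All tests in this part were chosen after the results were seen.

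Signals outside the comparisons above were tags with a run of at least 14 A and tags that equal the start of a mature miRNA. The A-run tags were 15.2% of B73 pollen and 14.1% of mop1 pollen, above the limit that a count of 0 allows. Tags equal to the first 20 nucleotides of miR159, TTTGGATTGAAGGGAGCTCT, numbered 1544 in the W23 2.0 to 3.0 mm library, 11 at 1.0 and 1.5 mm and 1 at 4.0 mm with pollen.

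The A-run tags set the pollen pair apart from the W23 libraries. In the pollen pair 92.6% and 93.4% of them start with the run, against at most 3.66% in the W23 libraries. Where 14 to 18 A led a tag of 20 nucleotides, GT followed in 97.5% of cases in B73 pollen and in 80.8% in mop1 pollen, and in the W23 libraries in 72.4% to 78.5% of far fewer such tags. These shares leave primer or adapter sequence behind the run open, because tags already seen among the 10 most abundant were 97.2% and 85.1% of those counted in the pollen pair, and among the other tags GT followed in 9.61% and 11.8%. Whether the pollen pair was prepared apart from the W23 libraries or the RNA itself differed cannot be told apart, because plant line and any difference in preparation coincide, and the 1 W23 library with pollen also holds anthers.

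The higher frequency of miR2275 and miR2118 cleavage tags at 2.0 to 3.0 mm was set against technical explanations. The 10 most abundant tags carried most of the miR2275 size: leaving them out took the miR2275 reads from 84890 to 11805. The words within 1 mismatch were then 5.31 times (miR2275) and 3.88 times (miR2118) as frequent as at 1.0 and 1.5 mm. With those tags they were 36.4 and 5.11 times as frequent. Whether the abundant tags are copies or separate molecules cannot be told, and tags 1 mismatch from those left out stayed in the count. These values therefore cannot decide whether copies of a few tags gave the difference. A library that caught more cleavage products of every miRNA is argued against by the ratio of 0.955 at the sites of other families, and exchanged labels of the later pair of W23 libraries by the 57.0% of tags specific to 4.0 mm with pollen that reach 10 TPM in B73 pollen, against 0.363% of those specific to 2.0 to 3.0 mm. Exchanged labels of the first 2 stages and differences between single plants or preparations were not tested and stay open. The level of the transcripts that are cut was not measured, so tag frequency alone does not show trigger activity. A rise of trigger activity at this stage may therefore be proposed only as a hypothesis, found and tested on the same 3 libraries.

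Tags with at least 20 TPM in one pollen library and under 1 in the other may partly reflect sequence variants between the plants. Of 355 such tags high in B73 pollen, 39.2% (34.2 to 44.3) had a partner in mop1 pollen. Of 513 high in mop1 pollen, 41.9% (37.7 to 46.2) had a partner in B73 pollen. A partner was a tag 1 mismatch away with at least 0.25 of the TPM of the first, with no upper limit. Tags called at like levels below lay within 2-fold of each other in the 2 libraries. Neighbouring tags are not independent, and with only the most abundant tag of each of the 75 and 169 groups of overlapping tags the shares were 45.3% (34.6 to 56.6) and 34.9% (28.1 to 42.4), against 4.90% and 3.70% in groups at like levels. Among tags at like levels in both libraries the shares counted by tag were 8.32% and 8.42%, while between the first 2 W23 stages they were 2.35% and 0% for tags that differ in the same way and 8.24% and 18.5% for tags at like levels (16.9% and 24.5% by group). The tags without such a partner, and any effect of the mop1 mutation, stay open, since the background of the mop1 plants is not given in the sources used here.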

How the results depend on the processing

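Alternatives chosen after the data were seen were those on A runs, on leaving out abundant tags, on base share, overlap and tags 1 mismatch apart, on at least 2 or 20 tags for families other than the triggers, on the leading miR169 site, and all for tags compared between libraries. Of 114 alternatives 48 gave values that stayed within the error or within 1.5-fold, 64 moved and 2 reversed. For every value below the cause was not tested. The miR169 value without its leading site is given with the result.

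With tags seen at least 2 times only, distinct tags numbered 2134190 in B73 pollen, 3531671 in mop1 pollen, and 4947728, 4028030 and 3118590 in the W23 libraries by anther length. Against shuffled words the families at 3 times their mean numbered 4 in B73 pollen, 4 in mop1 pollen (miR396, miR444, tasiR-ARF and, by the miR2118b word alone, miR2118 in both), and 8, 9 and 4 in the W23 libraries. At 1.0 and 1.5 mm a word of 9 nucleotides gave 2 families and 1 mismatch gave 0. At 4.0 mm with pollen 1 mismatch gave 0 and distinct sequences gave 0.

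The 2.0 to 3.0 mm library stayed above both others for miR2275 and miR2118 under every alternative run. Against 1.0 and 1.5 mm the miR2275 ratio was 38.4 with 9 nucleotides, 36.2 with 1 mismatch, 3.48 for distinct sequences, 41.9 without the most abundant tag and 4.22 without the top 10. The miR2118 ratio was 10.96, 6.12, 2.75, 22.2 and 8.52 in the same order. Against 4.0 mm with pollen miR2275 had 104 with 9 nucleotides, 30.5 with 1 mismatch, 6.99 for distinct sequences and 9.33 without the top 10, and miR2118 had 19.8, 7.05, 4.83 and 18.7. Between mop1 and B73 the miR156 ratio reversed to 0.857 with 1 mismatch and 0.869 for distinct sequences, and the miR529 ratio moved to 0.919 for distinct sequences. All values for distinct sequences were scaled by total tags.

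Rebuilt sites of other families numbered 78 at a penalty up to 5 and 24 with at least 20 tags. For miR2275 they numbered 10 at a penalty up to 3, 61 up to 5 and 42 with at least 2 tags. By base share and overlap, other families had 37 sites against a shuffled mean of 3.4 at 50% and 14, 19 against 2.33 at 80% and 14, and 80 against 18.3 at 5% and 14. They had 44 against 9.33 at 5% and 16, 44 against 11 at 1% and 16, 46 against 13.3 at 0.01% and 16, 34 against 9.67 at 0.01% and 17, and 1566 against 969 at 5% and 12. For miR2275 the same settings gave 16, 1, 29, 12, 12, 14, 10 and 245 sites, against shuffled means of 0.1, 0.333, 1, 0.333, 0.333, 0.333, 0.333 and 125. The count of 0 sites for miR2118 became 2 at a penalty up to 5 and 99 at 5% and 12, and stayed 0 in the other settings run. At 5% and 12 all families together had 1910 sites against a shuffled mean of 1205. Shuffled means for miR2118 alone were not kept for these settings, so neither the 2 nor the 99 is shown to be beyond chance.

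With 5 TPM added, tags 4-fold higher and lower at 2.0 to 3.0 mm than at 1.0 and 1.5 mm numbered 213 and 1068 of 5169. They numbered 1921 and 7343 of 59955 from 2 TPM, and 73 and 359 of 479 from 50. The shares higher and lower were 16.2% and 46.0% from 10 TPM, 3.20% and 12.2% from 2, and 15.2% and 74.9% from 50. At 4.0 mm with pollen against 2.0 to 3.0 mm the same settings gave 4239 and 836 of 10626, 28187 and 9653 of 88301, and 415 and 96 of 533. For mop1 against B73 they gave 916 and 678 of 14270, 6223 and 4302 of 76145, and 166 and 121 of 1377.

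Not run were the versions set out for genes, gene lists and codon periodicity and the target categories, which need transcript sequence, and the word of 12 nucleotides, since bases past the tenth lie outside the site. No paired analysis was possible because each group had 1 library. Depth limits a count of 0 to 0.0340 to 0.0787 TPM.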

Other observations

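All tests in this part were chosen after the results were seen.

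Production of phasiRNAs from a precursor could leave further tag starts at regular steps from the trigger's cut, since a second strand is cut in register with the first. Tags that begin within 1 mismatch of a word were taken here as cuts, with no longer site required. Sequence downstream of miR2275 cuts was rebuilt from overlapping tags of the 2.0 to 3.0 mm library into 6 separate stretches without long A runs. Among the 49 offsets from 12 to 60 nucleotides, the offset of 24 had rank 1 and that of 48 rank 2 in mean excess of tags over neighbouring offsets. This is consistent with further cuts at 24-nucleotide steps, but the stretches are few. Of the 5 with a tag at 24, one had 1 tag there, with 5 at 21 and 7 at 42. That stretch had 20 tags at the cut against 992 in the next 60 nucleotides together. For miR2118 the offset of 21 had rank 21 of 49 over 11 stretches, while 42 had rank 5 and 48 rank 3. In all 11 the cut held fewer tags than the next 60 nucleotides together (128 against 4779, 97 against 6580 and 47 against 5112 in 3 of them), so the test says nothing about steps of 21 nucleotides. Stretches with A runs were left out after they had been seen to give equal counts at many offsets.

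Tags that equal the first 20 nucleotides of a mature miRNA could be ends left when the miRNA is cut from its precursor. Of 11 miRNAs with at least 20 such tags in a W23 library, 10 had at least 10 times as many tags at the mature start as 1 nucleotide inside it, with 4187 against 312 tags over all 11. The exception was miR408, with 827 against 271 tags at 1.0 and 1.5 mm. The miR159 tags were 184 times as frequent at 2.0 to 3.0 mm as at 1.0 and 1.5 mm (103 to 370). Of 12 miRNAs in this comparison 3 had an interval above 1, the others being miR2118b at 9.64 (6.02 to 16.2) and miR2275b at 1.94 (1.35 to 2.82). Another 5 had an interval below 1, with ratios of 0.128 for miR164, 0.138 for miR168, 0.144 for miR528, 0.194 for miR408 and 0.204 for miR390. Mature miRNAs are not polyadenylated, and whether these tags come from precursors or from captured miRNAs was not tested.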
